A study of Drosophila melanogaster with 2 samples.

How the data were processed

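The samples were chromatin immunoprecipitations followed by sequencing (ChIP-seq) from whole Drosophila melanogaster pupae aged 24 hours, males and females together. The flies carried a transgene for the CG15710 protein with GFP fused to its C-terminus, and, per the labels, an antibody against GFP was used to precipitate it from sonicated chromatin. There was 1 group with 2 biological replicates, numbered 1 and 3 in the labels, so no comparison between groups of animals was possible. Tests were therefore made over peaks, genes or genome positions, which are not independent replicates, and each p-value describes these lists rather than the spread between animals.

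The deposited files were 4 peak lists in narrowPeak format on genome build dm6. One list was called for each replicate, 1 for the pooled replicates, and 1 held the peaks that passed the authors' irreproducible discovery rate (IDR) step. Such a step uses how alike peaks rank in replicates. The list it gave here was exactly the 8483 pooled peaks of highest signal, so a single peak in it need not rank alike in both replicates. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. Per the file headers and the descriptions deposited with the lists, each list other than the IDR list was made with a further input file that is not described, and a control experiment was not analysed here. The deposited signal of a peak is its own value within its list, on a scale that is not stated, and was used only to rank or describe peaks within a list, or to correlate ranks of matched peaks. The deposited −log10 q-value was at its maximum of 4.37 for all IDR peaks and was not used for ranking. Column 8 of each list held -1 throughout and was not used. The replicate lists and the pooled list each held exactly 30000 peaks, a number that looks like a cap set by the caller, so the weak end of these lists does not mark the end of detectable binding. The lists hold no read counts, so the depth of each library is unknown, and the intervals given for shares cover counting of peaks or genes only.

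Each peak was placed by its summit (start plus the offset in column 10). Genes came from Ensembl release 115 (annotation BDGP6.54, the same assembly as dm6), without transposable elements, and sequence came from the RefSeq copy of that assembly. The 6 arms 2L, 2R, 3L, 3R, 4 and X were used, and 0 peaks lay on other sequences. A summit within 500 bp of any of 23998 distinct transcription start sites (TSSs) was counted as promoter. Other summits were assigned in the order 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic. Expected shares came from 100000 circular shifts of the summits within each arm over bases that are not N, with a two-sided permutation p. The smallest value such a test can give is 2e-05, or 2e-04 for alternatives with 10000 shifts. Overlap of the replicates was tested by shifting the lists against each other in the same way, with at least 1 bp counted as shared.

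A gene was called bound when an IDR summit lay within 500 bp of any of its TSSs. The 22 gene lists were each compared with the other protein-coding genes (13945 in total), or, for tRNA, snRNA and snoRNA genes, with all other annotated genes (18164 in total). Two-sided Fisher's exact tests were adjusted by Benjamini-Hochberg over the 22 lists, and odds ratios had 0.5 added to each cell. A divergent promoter was a gene whose most upstream TSS had an opposite-strand TSS of another protein-coding gene within 1000 bp upstream. The 24 motif consensus strings and all 2080 6-mers were scored as present or absent in the 101 bp centred on each summit and in the 101 bp centred 300 bp to its left, with an exact McNemar test adjusted by Benjamini-Hochberg. Chromosome shares were tested with an exact binomial test against the share of bases. Shares have 95% exact Clopper-Pearson intervals.

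The gene lists, motifs, tests, most alternatives and the rule for named genes were set before the data were examined. The rule named CG15710, the genes at the 10 IDR peaks of highest signal within 500 bp of a protein-coding TSS, the genes overlapping or nearest to the 5 strongest IDR peaks with no TSS within 500 bp, and up to 3 bound members of each list with the strongest summit. The base composition of summits was examined after the data were seen. Alternatives were the 4241 IDR peaks of highest signal, each replicate's own 8483 strongest peaks (without the other replicate), promoter windows of 250 and 1000 bp, other overlap rules, the right flank, a 201 bp motif window with the flank moved to 500 bp, dinucleotide-shuffled sequences, and lists matched on the number of TSSs. The match on the number of TSSs treated all genes with many TSSs alike, so it was only approximate for them. Lists matched on promoter base composition and summits counted only for the gene of the nearest TSS, with 1000 circular shifts for the divergent promoters, were alternatives chosen after seeing the data.

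The tests were tested on simulated data. With 19.99% of 8459 random summits planted at TSSs, the location test estimated 20.8%, and with none planted 0 of 7 classes passed. With 60% of the members of 2 lists planted as bound in each draw, 100% of 400 planted lists passed, and with random bound genes 0.105% of 3800 lists did. Of the 24 motifs and 2080 6-mers, 0 passed at random summits. Random summits have no built-in difference in base composition from their flank, unlike the IDR summits (67.8% A and T against 54.7%). The simulation therefore does not show how the motif tests behave under such a difference. Random bound genes were likewise drawn without regard to their number of TSSs. A DREF site planted in 9.995% of the summits gave an excess over the flank of 10.01 percentage points. For replicate overlap, 49.998% of 29923 peaks were planted as shared and 49.98% were estimated. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.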

Results

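ChIP-seq located the CG15710 protein, tagged with GFP, on the chromatin of whole Drosophila pupae at 24 hours. CG15710 is a Drosophila gene known by its annotation number, and the assay title groups it with transcription factors. The group had 2 biological replicates (1 and 3). The IDR list held 8483 peaks in 8154 regions that did not overlap, covering 2.68 Mb, with a median width of 348 bp and signals from 159.0 to 9376 (median 329.4). These 8483 peaks were exactly the ones of highest signal in the pooled list of 30000. The lists give no read counts, so the sequencing depth behind each peak is unknown.

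The gene for the tagged protein carried no peak of its own. CG15710 (FBgn0034120) lies on the minus strand of 2R at 16347614 to 16348527 (dm6), and 0 peaks of any of the 4 lists overlapped it. The nearest IDR peak was 8756 bp away (2R, 16338717 to 16338857, signal 318.9) and the nearest pooled peak 2940 bp away.

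The first comparison asked whether both replicates marked the same sites. The strongest peak in both lists was the one upstream of CG14100, with ranks 1 and 1, and the intronic peak of CG11050 ranked 2 in replicate 1 and 4 in replicate 3. Of the 1000 strongest peaks of replicate 1, 848 (84.8%) overlapped a peak among the 1000 strongest of replicate 3, and all 1000 overlapped some replicate 3 peak. Over the full lists, 73.6% of replicate 1 peaks overlapped a replicate 3 peak, against 15.02% on average and 28.2% at most in shifted lists (permutation p = 2e-05, the smallest that 100000 shifts can give). In the other direction the share was 69.0%. Of the IDR peaks, 8217 (96.9%) overlapped a peak in each replicate. The IDR list was made from these same replicates, so a high overlap was built in. The signals of 22093 matched peaks had a Spearman correlation of 0.741 (permutation p = 1e-05, the smallest that 100000 permutations can give), and the 16315 pairs with summits within 100 bp had one of 0.849. These are correlations across peaks, which are not independent replicates. The named peak of Nrx-1 had no replicate 1 peak with a summit within 100 bp, and that of snoRNA:Me18S-A1576 had none in replicate 3.

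**Figure D1:**
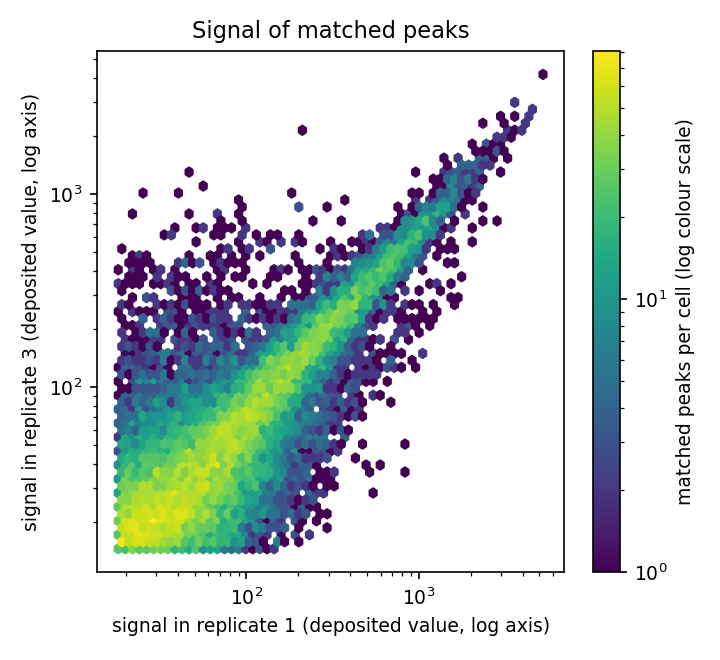
Signal of the 22093 matched peaks in replicate 1 (x axis) and replicate 3 (y axis), both as deposited and on log axes; the colour of each cell gives the number of peaks on a log scale. Points lie along a rising band (Spearman correlation 0.741), which is narrowest among the strongest peaks and widens among weak ones.

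The second comparison asked where in the genome the protein was bound. Promoters and introns together held most IDR summits, and coding sequence held almost none. Promoters held 3102 of 8483 summits (36.6%, 95% interval 35.5 to 37.6), 2.70 times the 13.6% of shifted summits (permutation p = 2e-05, adjusted over the 7 classes 3.5e-05). Coding exons outside promoters held 14 summits (0.165%, 0.0903 to 0.277) against 13.7% expected, and 3′ UTRs held 60 (0.707%, 0.540 to 0.910) against 4.44%, both with the same p. At positions drawn with the same base composition as the summits, an alternative chosen after seeing the data, the expected shares were 4.21% for coding exons and 7.55% for 3′ UTRs. Introns held 3586 summits (42.3%) against 39.5% (adjusted permutation p = 0.0038), an excess that ended with a promoter window of 1000 bp (35.8% against 36.2%, adjusted p = 0.646). At the positions matched on base composition introns held 43.8% (95% of draws 42.8 to 44.9), so there the intron share lay slightly below its expected level. Intergenic sequence held 1573 (18.5%) against 27.2% (adjusted permutation p = 3.5e-05). Noncoding exons held 98 (1.16% against 0.814%, adjusted permutation p = 0.0067), and the 50 in 5′ UTRs (0.589% against 0.782%) did not pass (adjusted p = 0.057). The noncoding exon excess ended without replicate 1 (adjusted permutation p = 0.109) and with a 1000 bp window (adjusted p = 0.388). The 5′ UTR deficit passed among the 4241 IDR peaks of highest signal, without replicate 1 and with a 1000 bp window (adjusted permutation p = 0.010, 0.0016 and 5.6e-04). Positions matched on base composition were drawn only for the full IDR list with the 500 bp window. They held 0.582% (0.424 to 0.743), which gave no deficit for the 0.589% observed there. Whether the deficits in the other settings would remain at matched positions was not tested.

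The sites that passed the IDR step lay at promoters more often than weaker ones. Of the 20111 pooled peaks that no IDR peak overlapped, 5094 (25.3%, 24.7 to 25.9) had a promoter summit (odds ratio 1.70, Fisher's exact test, two-sided, p = 4.4e-80). In coding exons, these weaker peaks had 654 summits (3.25%), also fewer than the 13.7% of shifted positions (permutation p = 2e-04).

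**Figure D2:**
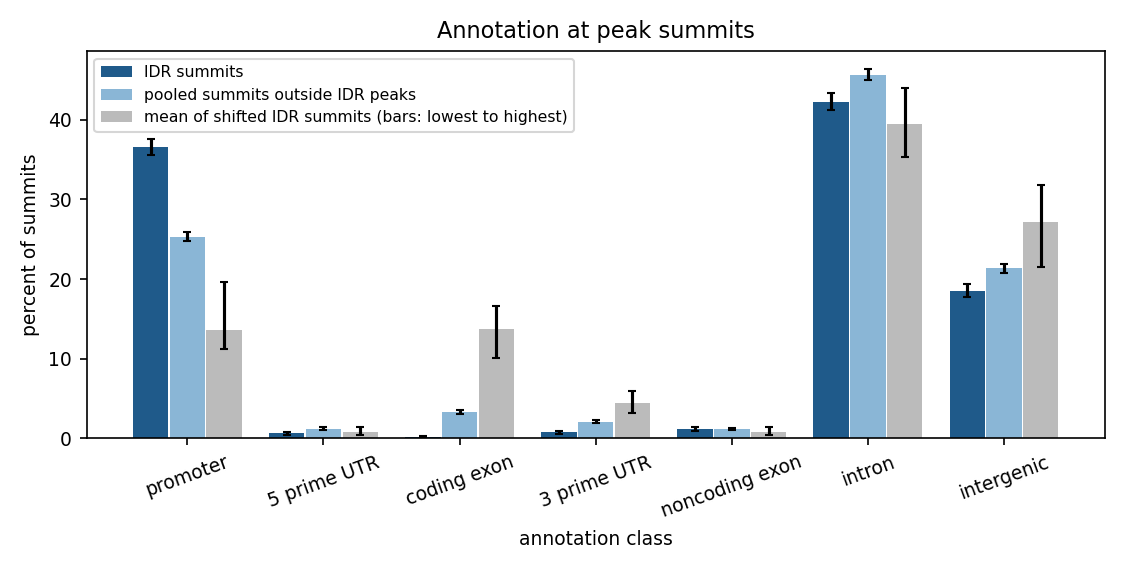
Percent of summits in each annotation class for IDR peaks (dark), for pooled peaks outside IDR peaks (light) and on average over shifted IDR summits (grey). Error bars are 95% exact intervals, or the lowest to highest shift for grey bars; promoters stand at 36.6%, 25.3% and 13.6%, and coding exons at 0.165%, 3.25% and 13.7%.

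At promoters, summits lay just upstream of the start site. Of the 2852 summits whose nearest protein-coding TSS was within 500 bp, 78.4% (76.8 to 79.9) were upstream, with a median of -116 bp and an interquartile range of -209 to -18 bp. The strongest IDR peak (3L, 19590384 to 19590845, signal 9376) had its summit at -90 bp from the TSS of CG14100. It was followed among promoters by a peak at an internal TSS of larp, which encodes a La-related RNA-binding protein (3R, 28326269 to 28326920, signal 7034, -326 bp). Next was Ugalt, the gene for a Golgi UDP-galactose transporter (X, 2703671 to 2704118, signal 6905, -38 bp). Genes of mitochondrial ribosomal proteins appeared in 2 of the 10 strongest promoter peaks. The peak of mRpL41 (2R, 15217561 to 15217980) had a signal of 6626 at -146 bp, and that shared by mRpS10 and Art3, an arginine methyltransferase gene, had a signal of 5995 (3R, 15229324 to 15229748), at -133 bp from the first TSS and -124 bp from the second. A further peak lay between the divergent genes Tcs5 and CHMP2B, the latter a component of the ESCRT-III membrane machinery, at -111 and -113 bp (3L, 5139294 to 5139711, signal 5435). The others were CG18549 (signal 6485, -136 bp), PNPase, a polynucleotide phosphorylase gene (signal 5406, -84 bp), Fkbp14 (signal 5272, -115 bp) and the Polycomb group gene ph-p (signal 5190, -475 bp). The ph-p summit was outside the promoter with a window of 250 bp.

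**Figure D3:**
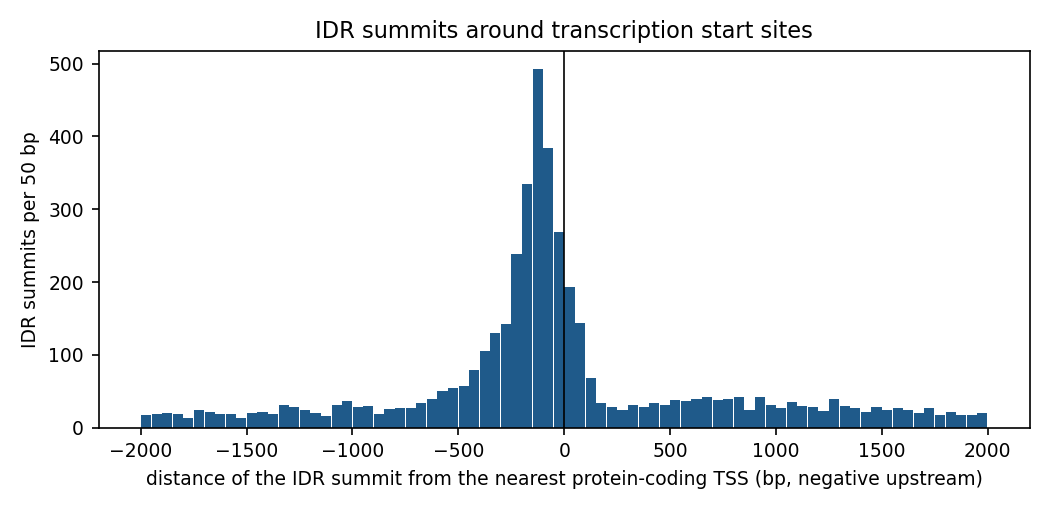
Number of IDR summits per 50 bp (y axis) by distance from the nearest protein-coding TSS (x axis, in bp, negative upstream). The highest bar, 493 summits, starts at -150 bp, and counts fall to 193 in the bin that starts at 0.

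Of the 5 strongest sites away from promoters, 3 lay in introns. The intronic peak of CG11050 (2L, 6612414 to 6612967, 1024 bp downstream of the nearest CG11050 TSS) had a signal of 7405, the second highest of the list. It was followed by an intronic peak of ush, which encodes a cofactor of GATA factors (2L, 480547 to 481351, signal 7038, 4859 bp downstream of the nearest ush TSS). A summit in introns of HmgD and of the overlapping gene HmgZ, both encoding HMG-box chromatin proteins, had a signal of 6542 (2R, 21703057 to 21703707). It lay at -613 bp from the nearest HmgZ TSS, so it falls inside the promoter with a window of 1000 bp. The other 2 were an intergenic summit 11915 bp from the TSS of CG13323 (2R, 13035003 to 13035604, signal 6414) and a summit in a noncoding exon (X, 12750792 to 12751697, signal 6258). The gene named for the latter, CG4004, has a TSS 5012 bp from the summit but ends at 12749785. The exon is therefore not part of CG4004, and the gene that holds it was not named.

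Chromosome 4 stood apart with few peaks. It held 26 IDR peaks, or 19.5 per Mb, which is 0.306% of peaks (0.200 to 0.449) on 0.996% of the bases (exact binomial test, two-sided, p = 1.4e-13). The X chromosome held 1648 peaks (70.2 per Mb), 19.4% (18.6 to 20.3) against 17.6% of bases (exact p = 8.5e-06), and 3L held 1899 (22.4% against 20.9%, adjusted p = 0.0018). Below their share of bases were 2R with 1465 peaks (17.3% against 18.9%, adjusted exact p = 2.0e-04) and 3R with 1918 (22.6% against 24.0%, adjusted p = 0.0035), and 2L did not differ detectably (18.0% against 17.6%, adjusted p = 0.325). The X excess did not pass among the 4241 IDR peaks of highest signal (18.6%, exact p = 0.069). The animals were of pooled sexes, so X was present at a lower mean copy number than the autosomes.

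The median signal of IDR peaks did not detectably differ between promoters and other sites. Promoter peaks had a median signal of 333.9 (interquartile range 216.9 to 648.6, n = 3102) and other IDR peaks 326.9 (219.1 to 587.9, n = 5381), a difference of 6.98 (permutation p = 0.351, two-sided). The difference was -10.1 in the strongest peaks of replicate 1 (permutation p = 0.026) and 11.5 in those of replicate 3 (permutation p = 2e-04), so its direction depended on the replicate. Among the 4241 IDR peaks of highest signal it was 49.8 (permutation p = 8e-04). In a split of the IDR peaks by signal into 10 groups, chosen after seeing the data, promoters held 44.3% of the 849 strongest peaks. They held 33.3% to 38.9% in the other groups, and the 38.9% was in the 848 peaks of lowest signal. The share was thus highest in the strongest group but did not rise steadily with signal. The differences between groups were not tested.

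Promoters of cytoplasmic ribosomal protein genes were the most often bound of the 22 lists. An IDR summit lay at 3426 of 13945 protein-coding genes (24.6%), and 15 of the 22 lists passed, 6 of them above other genes and 9 below. Of the 86 genes for cytoplasmic ribosomal proteins, 65 were bound (75.6%, 65.1 to 84.2, odds ratio 9.51, adjusted exact p = 6.2e-22). RpL34b (signal 1168), RpS27 (1138) and RpL32 (824 signal units) had the strongest summits of the list, all well below the top of the genome-wide ranking, at ranks 838, 881 and 1450. Among the 4241 IDR peaks of highest signal 36 of the 86 were bound (odds ratio 4.67, adjusted exact p = 1.0e-09). Of the 73 genes for mitochondrial ribosomal proteins, 37 were bound (50.7%, 38.7 to 62.6, odds ratio 3.18, adjusted exact p = 5.0e-06), with mRpL41, mRpS10 and mRpS23 at ranks 6, 11 and 29. The call for the mitochondrial list ended among the 4241 IDR peaks of highest signal (odds ratio 1.83, adjusted exact p = 0.124).

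Regulators of chromatin, ecdysone response, signalling and the cell cycle were also bound above the level of other genes. Of 41 genes for chromatin and insulator proteins, 24 were bound (58.5%, 42.1 to 73.7, odds ratio 4.32, adjusted exact p = 9.9e-06), among them ph-p, Chro (signal 4507), a chromodomain protein gene, and brm (signal 3226), the ATPase of the Brahma remodelling complex. In the list for the response to ecdysone, the steroid hormone of metamorphosis, 19 of 36 genes were bound (52.8%, 35.5 to 69.6, odds ratio 3.43, adjusted exact p = 7.0e-04). Sox14, a transcription factor gene induced by ecdysone, had a signal of 3086, the ABC transporter gene E23 one of 2600 and the cell death gene hid one of 2241. Of 49 signalling genes, 22 were bound (44.9%, 30.7 to 59.8, odds ratio 2.52, adjusted exact p = 0.0049), led by sgg, the GSK3 kinase gene (signal 2145), the Notch inhibitor gene numb (1953 signal units) and the atypical cadherin gene ft (signal 1722). Of 37 genes of the mitotic cell cycle and replication, 15 were bound (40.5%, 24.8 to 57.9, odds ratio 2.12, adjusted exact p = 0.049), with Dp (signal 1239), an E2F partner, and the replicative helicase genes Mcm2 (signal 837) and dpa (signal 568) the strongest. Against random lists matched on the number of TSSs, the ecdysone and cell cycle calls ended (adjusted permutation p = 0.088 and 0.155). The cell cycle call also ended among the 4241 IDR peaks of highest signal (adjusted exact p = 0.414) and against lists matched on promoter base composition (1.61 times the matched level, adjusted permutation p = 0.077). The signalling list depended on the replicate: 29 of 49 genes were bound without replicate 3 (59.2%, odds ratio 4.51, adjusted exact p = 6.3e-07) and 16 without replicate 1 (32.7%, odds ratio 1.495, adjusted p = 0.336), where the call ended. It also ended among the IDR peaks of highest signal (adjusted exact p = 0.301) and with a 250 bp window (adjusted p = 0.169).

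Genes for cuticle proteins, sensory receptors, antimicrobial peptides, eggshell and yolk, the male germline and histones were bound less often than other genes. Of 121 cuticle protein genes, 2 were bound (1.65%, 0.201 to 5.84, adjusted exact p = 1.1e-11), Cpr72Ea (signal 368.7) and Cpr12A (signal 270.8), with 0 bound at a window of 250 bp and 5 at 1000 bp. Of 179 odorant, gustatory and ionotropic receptor genes, 1 was bound, Gr77a (0.559%, 0.0141 to 3.07, adjusted exact p = 9.0e-20), and 3 were with a 1000 bp window. None of 17 antimicrobial peptide genes (upper 95% bound 19.5%, adjusted exact p = 0.019), 19 yolk and eggshell genes (upper bound 17.6%, adjusted p = 0.013) or 111 replication-dependent histone genes (upper bound 3.27%, adjusted p = 3.2e-13) was bound. The histone genes lie in near-identical repeated copies where reads cannot be placed uniquely, so their count is uncertain. In the male germline list, 1 of 23 genes was bound, bgcn (4.35%, 0.110 to 21.9, adjusted exact p = 0.041). The calls for antimicrobial peptides and male germline ended against lists matched on the number of TSSs (adjusted permutation p = 0.089 and 0.077). These and the yolk and eggshell call ended with a 250 bp window (adjusted exact p = 0.091, 0.094 and 0.061) and among the IDR peaks of highest signal (adjusted p = 0.241, 0.127 and 0.165). Antimicrobial peptides and yolk and eggshell genes had 0 bound genes in each of these settings, and male germline genes had 0 among the peaks of highest signal, so no lower count was possible there and the lost calls show no higher share. The male germline call also ended without replicate 3 (2 of 23, adjusted exact p = 0.133) and with a 1000 bp window (adjusted p = 0.057).

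Small RNA genes were likewise bound less often than other annotated genes, of which about 21% were bound. The counts were 24 of 290 tRNA genes (8.28%, 5.37 to 12.1, adjusted exact p = 1.5e-08), 15 of 269 snoRNA genes (5.58%, 3.15 to 9.03, adjusted p = 7.9e-12) and 1 of 32 snRNA genes (3.12%, 0.0791 to 16.2, adjusted p = 0.015). The strongest were tRNA:Tyr-GTA-1-8 (signal 2076), tRNA:Gln-TTG-2-1 (signal 1211) and tRNA:Lys-TTT-1-1 (signal 758.5). The strongest snoRNA gene was snoRNA:Psi28S-2949 (signal 698.5), and the bound snRNA gene was snRNA:7SKa (signal 232.2). The snoRNA call ended with a window of 1000 bp (adjusted exact p = 0.252). The number of snoRNA genes bound was 10 without replicate 1, 6 with a 250 bp window and 60 with a 1000 bp window, and 1 among the IDR peaks of highest signal. The snRNA call ended without replicate 3 (3 of 32, odds ratio 0.446, adjusted exact p = 0.177) and without replicate 1 (2 of 32, odds ratio 0.305, adjusted p = 0.075), against an odds ratio of 0.178 with the IDR list. It also ended among the IDR peaks of highest signal, where 0 snRNA genes were bound (adjusted exact p = 0.111), and against lists matched on the number of TSSs (adjusted permutation p = 0.088).

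In the other 7 lists the bound share was not detectably different from that of other genes. These were oxidative phosphorylation (19 of 79, 24.1%, adjusted exact p = 1), homeotic and patterning transcription factors (13 of 58, 22.4%, adjusted p = 0.799) and the proteasome (13 of 36, 36.1%, adjusted p = 0.166). Heat shock genes had 7 of 18 bound (38.9%, adjusted exact p = 0.222), sarcomere and muscle genes 4 of 29 (13.8%, adjusted p = 0.247), neuronal genes 3 of 24 (12.5%, adjusted p = 0.272) and ecdysteroid synthesis genes 2 of 13 (15.4%, adjusted p = 0.799). Strong single peaks occurred in these lists too, at the small heat shock gene Hsp27 (signal 4435), the neuronal RNA-binding protein gene elav (signal 2438), bowl (signal 2720) and ND-ASHI (signal 2030). Against lists matched on the number of TSSs, sarcomere and neuronal genes fell below the matched level (adjusted permutation p = 0.015 and 0.017). The proteasome rose above other genes with a window of 250 bp (adjusted exact p = 0.038).

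**Figure D4:**
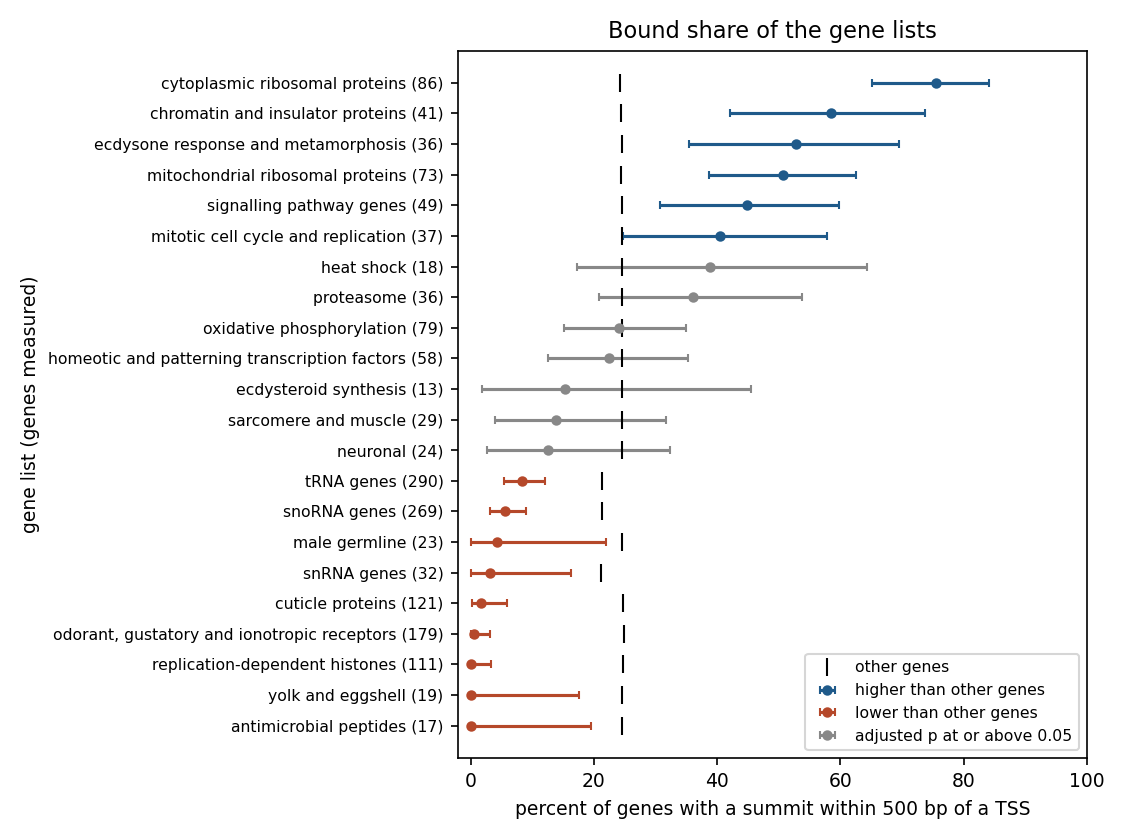
Percent of genes in each list with an IDR summit within 500 bp of a TSS (points, with 95% exact intervals) and the percent of other genes (vertical ticks). Lists above other genes are blue, lists below are red, and grey lists had an adjusted p of 0.05 or more; cytoplasmic ribosomal proteins stand highest at 75.6%.

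Bound genes often shared their promoter region with a divergent neighbour. Of 3426 bound protein-coding genes, 2027 (59.2%) had an opposite-strand TSS of another gene within 1000 bp upstream, against 2887 of 10519 genes without a summit (27.4%), an odds ratio of 3.83 (Fisher's exact test, two-sided, p = 1.7e-241). Circularly shifted summits gave 0.991 on average and 1.35 at most (permutation p = 0.0020, the smallest that 1000 shifts can give). A summit between 2 divergent TSSs can count for both genes. With each summit counted only for the gene of its nearest TSS, an alternative chosen after seeing the data, the odds ratio fell to 1.82, against 0.718 on average and 0.996 at most in shifts (permutation p = 0.0020). The pairs Art3 and mRpS10, and Tcs5 and CHMP2B, were among the 10 strongest promoter peaks.

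Known sequence elements were tested at the summits against the sequence 300 bp to the left. Of 24 motifs, 8 were more frequent at the summit, 9 less frequent and 7 did not pass. The TATA box string TATAAA occurred at 24.5% of summits and 9.07% of flanks (adjusted exact p = 5.1e-158), and the homeodomain string TAATTA at 10.7% and 5.01% (adjusted p = 1.0e-41). Core promoter motif 6 occurred at 4.77% and 1.70% (adjusted exact p = 1.0e-29), BEAF-32 at 5.02% and 3.02% (adjusted p = 1.1e-10), DREF (TATCGATA) at 0.967% and 0.330% (adjusted p = 5.1e-07) and Su(Hw) at 1.13% and 0.566% (adjusted p = 1.6e-04). GATA (3.48% and 2.82%, adjusted exact p = 0.022) and STAT (2.99% and 2.24%, adjusted p = 0.0036) were the others. The BEAF-32 string (TCGATA) lies within the DREF string, so the 82 summits with DREF are also among the 426 with BEAF-32. Less frequent at summits were CA repeats (1.53% and 4.48%), both E-boxes (CAGCTG 2.31% and 4.97%, CACGTG 0.519% and 1.52%), GAGA (1.61% and 2.99%), Zelda (1.59% and 2.46%), CTCF (0.790% and 1.53%), Pleiohomeotic (2.77% and 3.78%), Su(H) (0.872% and 1.40%) and Grainyhead (0.0472% and 0.236%). Without replicate 1 the ratio fell from 0.540 to 0.300 for GAGA and from 0.343 to 0.209 for CA repeats, and without replicate 3 these stood at 0.672 and 0.431. Among the 4241 IDR peaks of highest signal the ratios fell to 0.283 for GAGA, 0.201 for CA repeats, 0.293 for CTCF and 0.130 for Grainyhead. M1BP, core promoter motif 7, AP-1, FTZ-F1, the EcR/USP palindrome, the Initiator and HSF did not pass. Counted within 100 bp of the summit and against a flank 500 bp to the left, M1BP (ratio 2.73, adjusted exact p = 3.5e-09) and core promoter motif 7 (ratio 1.43, adjusted p = 1.9e-10) passed as more frequent, and AP-1 (ratio 0.738, adjusted p = 0.012) and FTZ-F1 (ratio 0.465, adjusted p = 0.0032) as less frequent. The GAGA, Grainyhead and STAT calls ended in that setting (adjusted exact p = 0.160, 0.349 and 0.194), and the STAT call ended against the right flank (adjusted p = 0.068). The first setting changed the window and the flank together, so the effect of each is unknown. Against the same sequences shuffled to keep their dinucleotides, the TATA box (ratio 1.03, adjusted exact p = 0.419), GATA (1.10 as a ratio, adjusted p = 0.358) and STAT (ratio 1.03, adjusted p = 0.818) calls ended and the homeodomain string became less frequent (ratio 0.810). In that comparison GAGA, CA repeats, CTCF and CAGCTG were more frequent at the summit than in its shuffled sequence, with ratios of 3.87, 3.58, 2.87 and 1.85. So were M1BP and core promoter motif 7 (ratios 13 and 1.72). Flanks were not compared with their own shuffled sequences, so a difference from shuffled sequence cannot be called particular to summits. The calls for DREF (ratio 6.6, against 2.89 with the flank), BEAF-32, core promoter motif 6 and Su(Hw) held against shuffled sequence, although the ratio of core promoter motif 6 fell from 2.81 to 1.31. Those of Pleiohomeotic (ratio 0.894, adjusted exact p = 0.315), CACGTG (ratio 0.679, adjusted p = 0.090), Grainyhead (ratio 0.818, adjusted p = 1) and Su(H) (ratio 1.34, adjusted p = 0.180) ended. Without replicate 3 the GATA call ended (adjusted exact p = 0.066), and without replicate 1 AP-1 passed as less frequent and HSF as more frequent (both adjusted exact p = 0.034).

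The search over all 6-mers returned strings rich in A and T. Of the 6-mers, 584 were more frequent at summits, 1169 less frequent and 327 did not pass. All 36 made only of A and T and all 192 with 5 such bases were more frequent, and all 36 with 0 and 192 with 1 were less frequent. The 10 with the highest ratio among those at 5% or more of summits were ATATTA, ATTATA, AATATA, TTTAAA, TACTAA, TATTAA, TCTTAA, TAGTAA, ATCTTA and ATATAA. The first occurred at 22.8% of summits and 5.75% of flanks, a ratio of 3.96 (exact McNemar test, adjusted p = 2.3e-220), and the last had a ratio of 3.11. Unlike the motifs, the 6-mers were not compared with shuffled sequences.

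The base composition behind these strings was measured after they were seen. The bases within 50 bp of IDR summits held 67.8% ± 9.21 A and T (SD over 8483 peaks), against 54.7% ± 9.54 in the left flank, 54.8% ± 9.55 in the right flank and 57.8% over the 6 arms. Summits at promoters held 66.4% ± 10.6 and other IDR summits 68.7% ± 8.22. In the pooled peaks outside IDR peaks the summits held 59.0% ± 10.6, close to their left flank at 56.9% ± 9.89. The summits of brm (84.2%), mRpL41 (78.2%) and CG11050 (78.2%) were above the mean, whereas those of RpS27 (49.5%), Hsp83 (48.5%) and snRNA:7SKa (26.7%) were well below it.

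**Figure D5:**
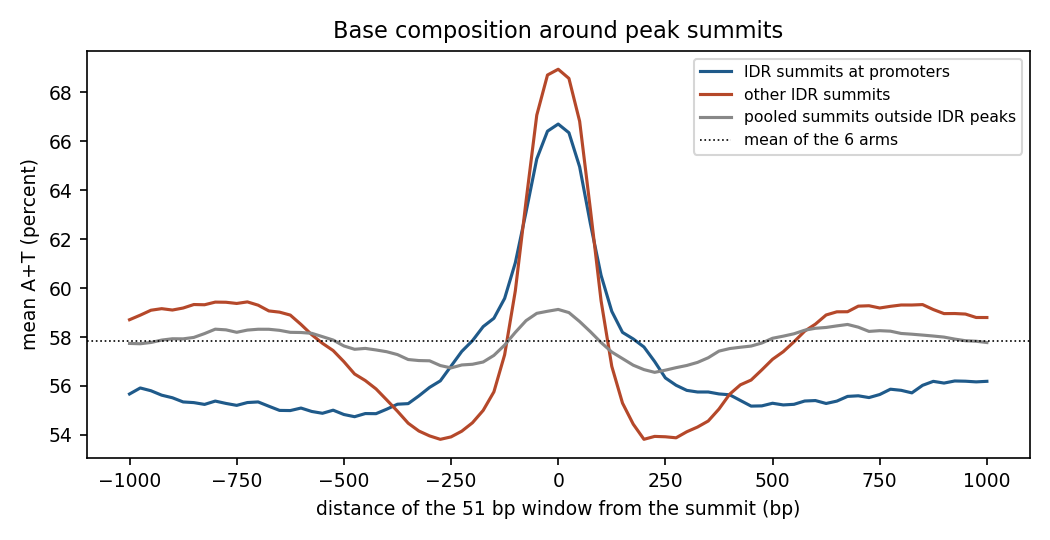
Mean percent of A and T (y axis) in 51 bp windows by distance from the summit (x axis, bp) for IDR summits at promoters, other IDR summits and pooled summits outside IDR peaks; the dotted line is the mean of the 6 arms. At the summit the lines stand at 66.7%, 68.9% and 59.1%, and the line for other IDR summits falls to 54.0% at -300 bp.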

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

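The direction and the test's side of the threshold held under every alternative run for the replicate overlap, the rank correlation, the promoter share (27.6% to 46.7% with windows of 250 and 1000 bp), the coding exon share, the promoter share against weaker peaks, the chromosome 4 share and the divergent promoters (odds ratios 3.39 to 4.23, and 1.82 with each summit counted for the gene of its nearest TSS only). The counts of motifs (7 to 10) and of 6-mers (547 to 618) more frequent at summits stayed within 1.5 times their main values. The 6-mers were not compared with shuffled sequences, so their count was not checked at equal base composition. The motifs behind the count changed, however, against shuffled sequences. Of those more frequent against the flank, only DREF, BEAF-32, core promoter motif 6 and Su(Hw) kept their call, and of those less frequent only Zelda did. The smaller changes below have no tested cause unless stated.

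Among the 4241 IDR peaks of highest signal, the X share fell to 18.6% and no longer passed (p = 0.069), the signal of promoter peaks exceeded that of others by 49.8 (permutation p = 8e-04), and 8 gene lists passed instead of 15, with fewer peaks behind each list (antimicrobial, male germline, yolk and snRNA genes were at 0 bound); the proteasome odds ratio was 0.881 and the ratio of core promoter motif 7 was 0.869, both reversed. The signal difference ranged from -10.1 to 11.5 when 1 replicate was left out and was -5.49 with a 250 bp window. Leaving out 1 replicate also gave odds ratios of 0.659 to 1.04 for ecdysteroid synthesis, 0.941 to 2.52 for heat shock and 1.00 to 1.11 for oxidative phosphorylation, and the last stood at 1.24 with a 250 bp window; none of these lists passed in any of these settings. Against dinucleotide-shuffled sequences, the ratios of 8 motifs turned. Those of GAGA (3.87), CA repeat (3.58), CTCF (2.87), CAGCTG (1.85) and the homeodomain string (0.810) passed. Those of the Initiator (1.11, adjusted exact p = 0.065), Su(H) (1.34, adjusted p = 0.180) and the EcR/USP palindrome (3) did not. The palindrome occurred at 1 summit and in 0% of shuffled sequences, too few to read. The shuffled sequences share the base composition of the summit by construction, which the left flank does not, and flanks were not compared with their own shuffled sequences. Matching lists on promoter base composition, chosen after seeing the data, ended the cell cycle call (ratio 1.61, adjusted permutation p = 0.077) and left 14 lists past the threshold, and homeotic and patterning factors turned to a ratio of 1.17 (adjusted permutation p = 0.651).

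The call was the same under each of 7 alternatives for 6 of 22 lists: cytoplasmic ribosomal proteins, chromatin and insulator proteins, cuticle proteins, the receptor list, histones and tRNA genes. For histones the count was 0 of 111 throughout, in repeated copies where reads cannot be placed uniquely, so the steady call adds no support. Over all lists and alternatives, 23 list calls ended and 3 were gained, and 12 motif calls ended and 8 were gained, and 5 motif calls passed in the opposite direction. A named gene lost its promoter summit in 38 cases, mostly with the 250 bp window or among the strongest peaks, and kept its status in 287. No paired analysis was possible because there was 1 group. With 2 replicates and no read counts, the error between animals and the depth behind a peak cannot be given.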

Other observations

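The tests of base composition, of the gene lists known for high expression, of peaks matched on signal and of mitochondrial genes with a divergent neighbour were chosen only after the results they bear on were seen. So was the use of an interval for the mitochondrial genes without such a neighbour. The design has 1 group, so no biological explanation was tested by a comparison of groups.

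Stronger IDR peaks had summits richer in A and T. The 849 IDR peaks of highest signal held 71.4% ± 6.76 (SD) within 50 bp of the summit, against 63.9% ± 10.5 in the 848 of lowest signal (Spearman correlation of base composition and signal across 8483 peaks 0.261, permutation p = 1e-05, the smallest that 100000 permutations can give). Peaks are not independent replicates. The enrichment was narrow: the mean was 65.5% within 100 bp of the summit, 61.2% within 200 bp and 58.1% within 400 bp, against 57.8% over the 6 arms. Chromosome 4, with 64.8% A and T the richest of the 6 arms, had the lowest density of peaks, and replicate 1 listed 191 peaks there and replicate 3 listed 66.

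The placement of the IDR summits could come from a preference of the protein, the library or the caller for A and T alone. The values argue against the A and T content within 50 bp as the whole cause. Positions drawn at random with the same base composition within 50 bp fell in promoters in 13.6% of cases on average (95% of 1000 draws 12.8 to 14.3), against 36.6% observed, and in coding exons in 4.21% (3.84 to 4.60), against 0.165%. For introns the matched share of 43.8% was slightly above the 42.3% observed, so base composition could account for the intron excess over shifted summits. Counting coding sequence inside promoter windows too, 0.507% of summits lay in it, against 17.0% on average and 14.3% at least in 10000 shifts, so the order of the classes does not account for its absence. The matched positions shared only the total of A and T within 50 bp. They were not matched on the fall from the summit (67.8%) to the left flank (54.7%) or on the order of bases. A preference for such local contrast was therefore not tested. Open chromatin and a mock precipitation were not analysed here, and both stay open as explanations.

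The binding of ribosomal protein genes could follow from their divergent promoters. Among genes without a divergent neighbour, 23 of 33 cytoplasmic ribosomal protein genes were bound (69.7%) against 15.3% of other genes (odds ratio 12.4, Fisher's exact test p = 3.8e-12), which argues against it for that list. For mitochondrial ribosomal protein genes, those with a divergent neighbour were bound more often than other such genes (34 of 58, 58.6% against 41.0%, odds ratio 2.02, exact p = 0.010), while the 15 without one gave an odds ratio of 1.53 (95% interval 0.247 to 5.07), too wide to tell the explanations apart. Signal at highly transcribed genes in general is another candidate explanation: 24.1% of oxidative phosphorylation genes were bound (95% interval 15.1 to 35.0) against 24.6% of other genes, but expression in these pupae was not analysed here, so this cannot be told apart from binding specific to ribosomal protein genes.

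Peaks found in 1 replicate only may be background calls near the weak end of each list. The 7907 peaks of replicate 1 only were at promoters in 28.0% of cases against 32.3% of its shared peaks (Fisher's exact test p = 8.8e-13), and the 9292 of replicate 3 only in 17.1% against 31.4% (p = 1.4e-155). These peaks were also weaker than shared ones (median signal 28.3 against 70.1 in replicate 1, and 20.2 against 45.1 in replicate 3), and weak true sites would differ in the same way. With shared peaks weighted to the same signal, the promoter share of replicate 1 only was the higher one (28.0% against 25.6%) and that of replicate 3 only the lower one (17.1% against 27.8%, permutation p = 0.0020 for both). The base composition of replicate 3 only did not differ detectably from that of shared peaks at matched signal (58.9% for both, permutation p = 0.785). That of replicate 1 only was lower (56.9% against 58.9%, permutation p = 0.0020). Coding exons held 5.74% of the peaks of replicate 1 only and 7.67% of those of replicate 3 only, against 1.10% and 1.15% of shared peaks. The coding shares were not compared at matched signal. At matched signal the replicates thus disagree, and background calls cannot be told apart from weak sites.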
